A study of Homo sapiens with 56 samples.

How the data were processed

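RNA sequencing was carried out on 56 human samples that the labels describe as colon muscle, 31 labelled post-infection irritable bowel syndrome (PI-IBS) and 25 labelled healthy volunteer (HV). Per the labels, total RNA was extracted with Trizol, kept in RNAlater and made into libraries with an Illumina TruSeq Stranded kit. FastQC, STAR, HTSeq, edgeR and the genome build hg38 are named in the submitters' processing notes, without roles or versions. The annotation release and the filter that set the genes in the table are not given in the sources used here.

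The deposited table is a score per gene and sample, that is, a read count multiplied by 1 factor per sample by the authors and rounded to whole numbers, and it held 17408 genes. The values showed this: in 29 libraries some whole numbers below 60 never occurred, as rounding after multiplication by a factor above 1 leaves them. The factor was read from these gaps, and from whole numbers that occurred in excess, among values up to 300. It was resolved in 55 libraries, and in simulated libraries 29 of 30 factors were resolved, all 29 within 1% of the truth. Reads per library were estimated as the library total divided by its factor. Whole reads could not be recovered for nearly all genes, because rounding after a factor below 1 merges neighbouring counts, so no count model was run. Counting error is small against the spread between samples at these depths, and the number of samples limits the precision.

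Values were divided by 43.5, the mean library total over 1000000, the same divisor for every library, and are given as normalized units per 1000000 units (NPM; the axes of the plots write this in words). Genes entered a test with at least 1 NPM in at least 25 samples, which left 16274 genes; 1128 fell below that filter. XIST and Y-linked genes were left out. Tests ran on log2(value + 1 NPM) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A difference on this scale understates the change of low genes. All 56 samples entered 1 fit with no covariate, as the design text names none. In simulated data with the real means and spreads of the 16274 genes, the fit for genes called 16.4% of genes changed by 0.25 on the log2 scale, 77.6% of those changed by 0.5 and 97.0% of those changed by 1. Genes were simulated as independent, whereas the first principal component took 27.8% of the variance of the real values. The real fit can therefore call more or fewer than these rates.

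Lists of 35 gene groups, 785 entries in all, and 24 candidate genes were fixed before the data were examined, as were the tests, the naming rule and most of the alternative settings. Through current and older symbols, 691 list entries matched the table. Lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. The mean log2 value of a list in each sample, its list score, was compared by a two-sided permutation test with 100000 resamples. Means are given ± SD over samples, and log2 differences ± SE. The naming rule takes the genes past the threshold with a symbol (up to 10 each way by p, then up to 5 each way by fold), or the 4 lowest-p genes of a direction in which none passed, all tested candidates, the 3 lowest-p members of each list called by camera, and the lowest-p member of other lists. Clone names, pseudogenes and immunoglobulin or T-cell receptor segments are outside the rule. CCDC162P, a pseudogene past the threshold, and list members beyond the rule were named after their values were seen.

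Alternatives covered the pseudocount, the filter, quantile normalization, recomputed TMM factors, sample weights, robust moderation, covariates, a subset of samples, single libraries left out and a rank test. Sample titles come in 2 forms, 10 with the letters TRNA (9 PI-IBS, 1 HV) and 46 without; what the letters mean is not given in the sources used here. With 1 HV sample among them, the 10 give no comparison of their own, so values within the 46 stand beside pooled ones. No 2 libraries were identical, and over abundant genes the closest pair differed by 21.2 times the variance of counting noise. The labels do not say that each sample came from a separate person, so p-values measure the spread between these samples. Python 3.11.15 and matplotlib 3.10.9 were used for depth estimates and plots. Coordinates are hg38, as the table gives them. Transcript length and GC content were those of each gene's longest GENCODE transcript on the same assembly, matched by identifier for 17126 of the 17408 genes.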

Results

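Gene expression was profiled in 31 colon samples labelled PI-IBS, bowel symptoms that begin after an intestinal infection, and 25 labelled healthy volunteer. The design asks which genes of the intestinal wall differ between the groups. Estimated depth in units of 1000000 reads was 30.1 to 79.2 per library over 55 libraries. It was higher in PI-IBS, at 45.9 ± 9.73 (SD, n = 30), than in HV, at 39.99 ± 5.81 (SD, n = 25; permutation test, two-sided, p = 0.00748). The number of genes listed at 0 ran from 17 to 1343 per library. Its median was 98 in HV and 60 in PI-IBS (permutation test of the means, p = 0.00442; p = 0.0268 within the 46 titles without TRNA).

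The libraries carried abundant transcripts of the colon's surface epithelium. PIGR, which carries antibodies across the epithelium, stood at 7136 ± 2205 normalized units per 1000000 (NPM; SD, n = 56), FABP1, a fatty acid binding protein of enterocytes, at 3682 ± 1774, and LGALS4, an epithelial galectin, at 3294 ± 960.3. Smooth muscle transcripts were lower, with MYH11, the smooth muscle myosin heavy chain, at 216.7 ± 256.7, ACTA2 at 207.2 ± 65.86 and DES (desmin) at 121.7 ± 126.4. The epithelium list took 4.68% ± 0.758 of the library total in HV and 4.79% ± 0.670 in PI-IBS, and the smooth muscle contractile list 0.441% ± 0.0704 and 0.415% ± 0.158. The epithelial share was the higher in 56 of 56 libraries, by 11.6 times at the median and 3.66 times at the lowest. The epithelial share did not differ detectably between the groups (permutation test, p = 0.555, 0.817 after adjustment over 10 shares). The muscle comparison rests on 1 library: with all 56 p was 0.549 (adjusted 0.817), and without PI-IBS replicate 27, at 1.19%, the share was lower in PI-IBS, at 0.390% ± 0.0685 (SD, n = 30; p = 0.00868, adjusted 0.0289). Most of that difference was MYL6, a broadly expressed myosin light chain, at 0.211% in HV and 0.172% in PI-IBS; the other members summed to 0.230% and 0.218% (p = 0.447). Within titles without TRNA, also without that library, it was 0.439% in HV and 0.399% in PI-IBS (adjusted p = 0.226).

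**Figure D1:**
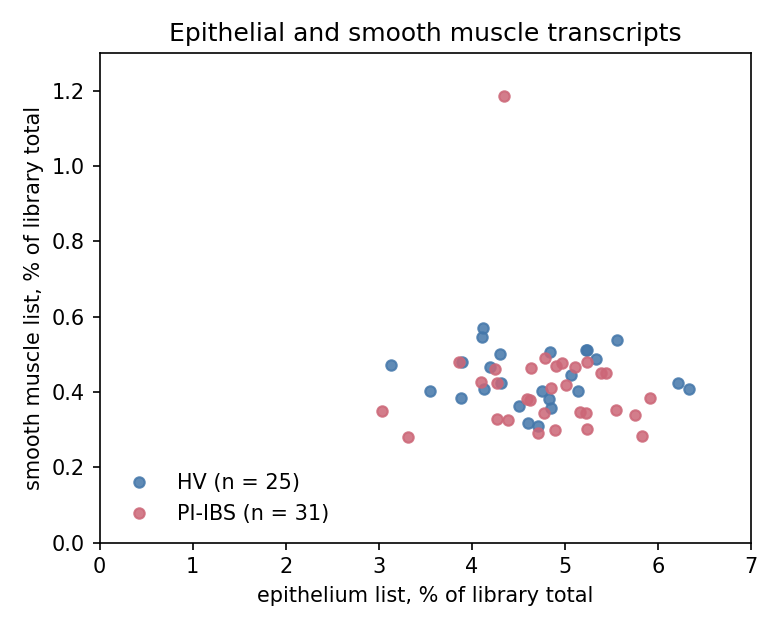
Share of each library's total taken by the epithelium list (x axis, %) and by the smooth muscle contractile list (y axis, %); each point is 1 library, blue HV (n = 25) and red PI-IBS (n = 31). The epithelial share was higher in 56 of 56 libraries, and 1 PI-IBS library has a muscle share of 1.19%, with the other PI-IBS libraries at up to 0.489% and HV at up to 0.569%.

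The smooth muscle and epithelium scores were inversely related across the 56 samples. Pearson's r was -0.27 (permutation p = 0.0443) and Spearman's rho -0.37 (p = 0.00516). Within HV r was -0.51 (p = 0.00961), within PI-IBS -0.14 (p = 0.442), and within titles without TRNA -0.40 (p = 0.00613). Without the 2 samples farthest from the median muscle score r was -0.40 (p = 0.00248).

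Against healthy volunteers, 4 genes were raised in PI-IBS and 0 were lowered (limma, adjusted p below 0.05, 16274 genes tested). GABRE, the epsilon subunit of the GABA-A receptor (ENSG00000102287, chromosome X, 151953124 to 151974680), rose from 19.3 ± 8.77 to 30.5 ± 8.84 NPM (SD, n = 25 and 31), a log2 difference of 0.71 ± 0.14 (SE, limma adjusted p = 0.0238). ZNF587, a zinc finger gene (ENSG00000198466, chromosome 19, 57849857 to 57865112), rose from 32.5 ± 9.33 to 46.7 ± 12.0, by 0.52 ± 0.10. C1orf220 (ENSG00000213057, chromosome 1, 178542752 to 178548889) rose from 1.35 ± 0.863 to 2.57 ± 0.984, by 0.63 ± 0.12, at the same adjusted p. CCDC162P, a pseudogene (ENSG00000203799, chromosome 6, 109285485 to 109355063), rose from 12.0 ± 4.43 to 19.5 ± 6.93, by 0.67 ± 0.14 (limma adjusted p = 0.0279).

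**Figure D2:**
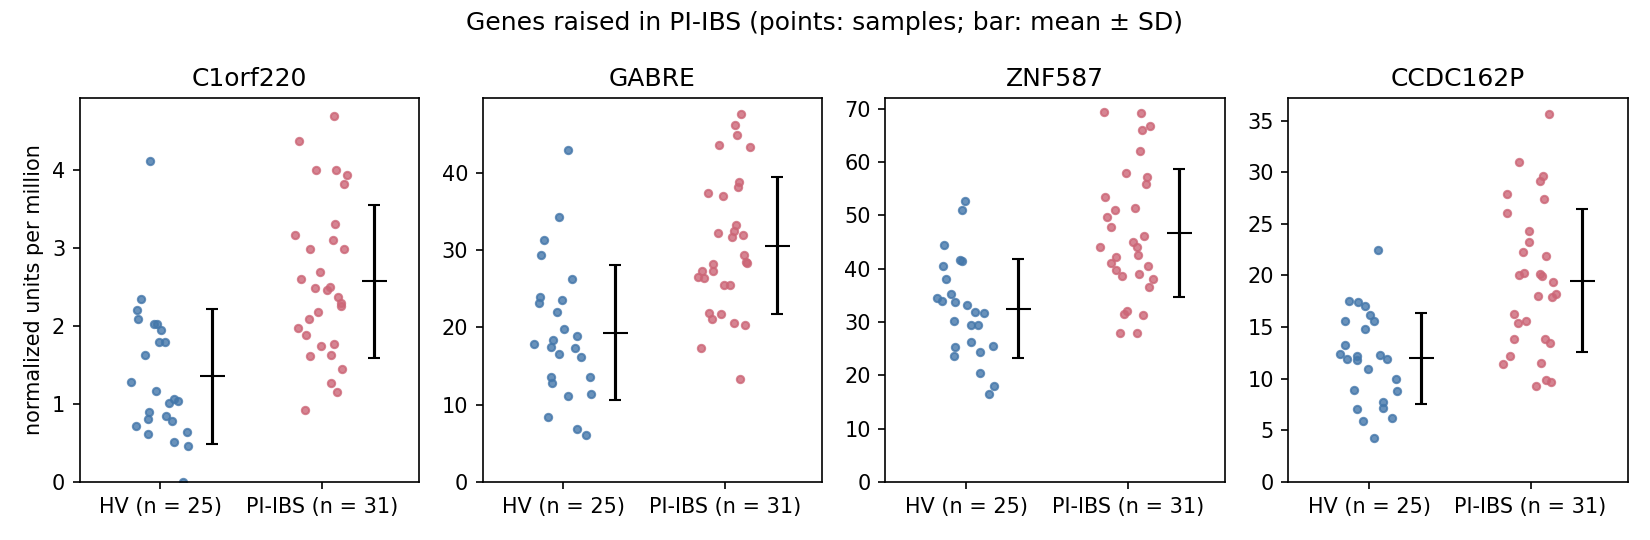
NPM (y axes, from 0) of C1orf220, GABRE, ZNF587 and CCDC162P in each sample, by group; black bars are the mean ± SD. The groups overlap for each gene, and the PI-IBS mean is the higher, as for GABRE at 30.5 against 19.3.

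None of the lowered genes passed. The 4 with the lowest p each had a limma adjusted p of 0.0605. They were MT-TD, the mitochondrial tRNA for aspartate (log2 difference -0.82 ± 0.18, SE), HES1, a Notch target (-0.41 ± 0.09), TRAPPC4, of the TRAPP trafficking complex (-0.28 ± 0.06), and MRPL28, of the mitochondrial ribosome (-0.54 ± 0.13). An unadjusted p below 0.05 was reached by 4421 genes, 2016 higher and 2405 lower in PI-IBS, against 814 expected if no gene differed. Adjusted values were tied, with 541 genes at the adjusted p of 0.0605. A Wilcoxon rank-sum test called 0 genes, with 4025 at an unadjusted p below 0.05. Within titles without TRNA limma called 0 genes (3861 at an unadjusted p below 0.05), with GABRE at 0.69, ZNF587 at 0.53, C1orf220 at 0.58 and CCDC162P at 0.65 (limma adjusted p = 0.111 for each). Without HV replicate 25, the library with 1343 genes at 0, limma called 0 genes (3580 at an unadjusted p below 0.05; adjusted p = 0.0522 for GABRE, a log2 difference of 0.65), and with the log2 number of genes at 0 as a covariate it called 0 (836 at an unadjusted p below 0.05), with GABRE at 0.50, ZNF587 at 0.37, C1orf220 at 0.47 and CCDC162P at 0.64. With the first principal component as a covariate it also called 0 (693 at an unadjusted p below 0.05), with GABRE at 0.42, ZNF587 at 0.30, C1orf220 at 0.44 and CCDC162P at 0.62. The counts of 836 and 693 lie near or below the 814 expected with no effect. The excess of low p-values thus cannot be told apart from the number of genes at 0. The first component was taken from values with the group difference left in, so it can also absorb a group effect. With sex-linked expression as covariates 2 of the 4 stayed, ZNF587 at 0.43 and C1orf220 at 0.55, while GABRE at 0.61 and CCDC162P at 0.66 did not pass (limma adjusted p = 0.0587 for both; 2577 genes at an unadjusted p below 0.05). With each library left out in turn the count was 0 for 2 of 56 (HV replicates 22 and 25) and over 100 for 14, up to 1614 without PI-IBS replicate 20.

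Of the 24 candidate genes, 18 were tested, and 1 was raised when adjusted over the list alone. TJP1, which encodes the tight junction scaffold ZO-1 (chromosome 15, 29699367 to 29968865), rose from 52.5 ± 22.4 to 70.1 ± 22.96 NPM, a log2 difference of 0.46 ± 0.14 (SE, limma adjusted p = 0.0363 over the list alone, 0.0605 over all genes). Over all genes tested 0 candidates passed. An unadjusted p below 0.05 was reached by 3 of the 18 in limma, against 27.2% of all tested genes. CHRM3, the muscarinic receptor of gut smooth muscle, differed by 0.27 ± 0.10 (unadjusted p = 0.0110) and TRPV1, a pain-sensing channel, by 0.19 ± 0.09 (p = 0.0327), neither passing. Within titles without TRNA TJP1 differed by 0.49, and without HV replicate 25 by 0.39, and in both limma called 0 candidates over the list alone. With the number of genes at 0, the estimated reads or the first principal component as a covariate TJP1 was at 0.24, 0.29 and 0.11, and with sex-linked expression as covariates at 0.34, again with 0 candidates passing, and 0 passed in 19 of 56 fits that each left out 1 library.

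For the other 15 candidates the 95% interval of the difference took in 0. Among muscle and pacemaker genes the log2 differences were 0.22 ± 0.13 for CACNA1C, 0.13 ± 0.08 for KCNMA1, -0.21 ± 0.13 for ACTA2, 0.10 ± 0.21 for MYH11, 0.15 ± 0.16 for KIT and 0.03 ± 0.14 for ANO1. Among nerve, glia and receptor genes they were 0.19 ± 0.30 for VIP, -0.20 ± 0.12 for S100B and -0.02 ± 0.18 for TACR2. The serotonin-synthesis gene TPH1 was at 0.08 ± 0.19. Immune genes lay at 0.26 ± 0.14 for CD163, 0.12 ± 0.33 for IL1B, 0.09 ± 0.17 for TNF and 0.14 ± 0.32 for CXCL8, and the adhesion gene CDH1 at 0.18 ± 0.10. NOS1, IL6 and HTR4 were below the filter, with medians of 0.046, 0.23 and 0.644 NPM. CHAT and SLC6A4 were not analysed here.

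Transcripts for ribosomal proteins were lower in PI-IBS in 41 of 41 tested members, with a median log2 difference of -0.38 (camera adjusted p = 2.0e-22, but adjusted p = 0.979 with an estimated correlation). RPS2 was at -0.48 ± 0.12 (SE), RPL37 at -0.44 ± 0.12 and RPS21 at -0.60 ± 0.16. Adjusted over the list alone 41 members were lowered, and over all genes 0. Their summed share of the library was 4.44% ± 1.46 in HV and 3.55% ± 0.858 in PI-IBS (SD; permutation test, adjusted p = 0.0253), and 4.42% and 3.52% within titles without TRNA, where it did not pass (adjusted p = 0.0702). The list score differed by -0.38 ± 0.12 (SE; permutation test, adjusted p = 0.0536), and by -0.39 within titles without TRNA (adjusted p = 0.0567).

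Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were lower in 28 of 32 members, with a median of -0.27 (camera adjusted p = 2.2e-10, but adjusted p = 0.979 with an estimated correlation). NDUFA2 was at -0.43 ± 0.12 (SE), COX7C at -0.31 ± 0.09 and COX4I1 at -0.37 ± 0.11. Adjusted over the list alone 24 members were lowered, and over all genes 0. The list score differed by -0.23 ± 0.07 (permutation test, adjusted p = 0.0551), and by -0.25 within titles without TRNA.

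Immediate early genes, which respond within minutes to stimulation or handling, were lower in 22 of 24 members, with a median of -0.27 (camera adjusted p = 0.0323, but adjusted p = 0.979 with an estimated correlation). IER2 was at -0.65 ± 0.23 (SE), JUND at -0.70 ± 0.25 and JUNB at -0.61 ± 0.24, and 0 members passed over the list alone. Without HV replicate 25 their median was -0.20, which did not pass (camera adjusted p = 0.0641). With fry the adjusted p was 0.0605 for ribosomal proteins, 0.0675 for oxidative phosphorylation and 0.630 for immediate early genes, so that camera's 3 calls all fell away with the estimated correlation and with fry.

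Both the ribosomal and the oxidative phosphorylation score moved with the number of genes listed at 0. For ribosomal proteins r with its log2 was 0.71 over 56 samples (permutation p = 1e-05, the smallest the resamples allow, and 1e-05 after adjustment over 2 relations; rho 0.56). It was 0.75 within HV, 0.54 within PI-IBS, 0.75 within titles without TRNA and 0.63 without the 2 samples farthest from the median. For oxidative phosphorylation r was 0.70 (p = 1e-05; rho 0.66), 0.74 within HV, 0.52 within PI-IBS, 0.71 within titles without TRNA and 0.66 without the 2 farthest samples.

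**Figure D3:**
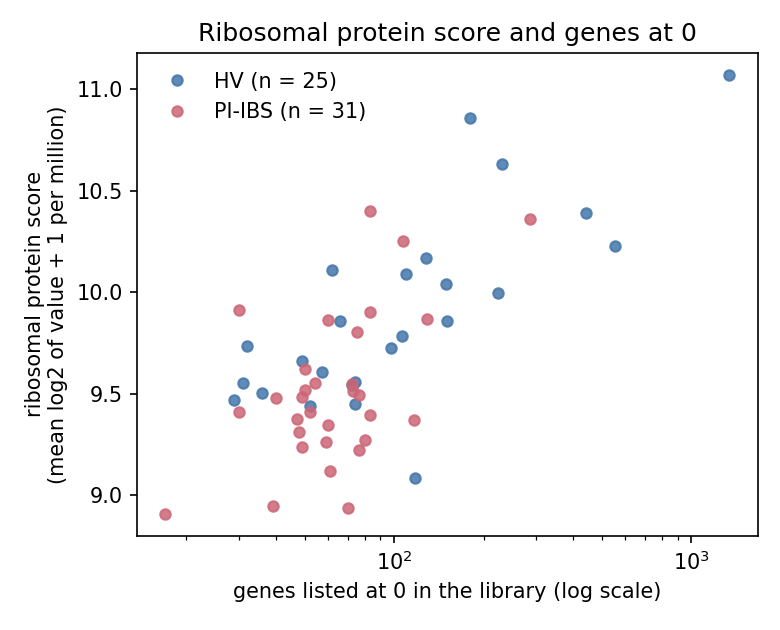
Ribosomal protein score (y axis, mean log2 of value + 1 NPM) against the number of genes listed at 0 in the library (x axis, log scale); each point is 1 library, blue HV (n = 25) and red PI-IBS (n = 31). The score rises with the number of genes at 0 within both groups, with r of 0.75 in HV and 0.54 in PI-IBS, and the library at 1343 genes is an HV sample.

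Tight junction and barrier genes moved both ways. Of 17 tested members, 4 were raised and 1 lowered when adjusted over the list alone, and 0 passed over all genes. In limma 7 of the 17 had an unadjusted p below 0.05, against 27.2% of all tested genes. Among them OCLN (occludin) was at 0.54 ± 0.21 (SE) and CGN (cingulin) at 0.34 ± 0.13, beside TJP1 at 0.46, while CLDN3 (claudin-3) was at -0.51 ± 0.18. With the first principal component as a covariate TJP1 was at 0.11, and OCLN, CGN and CLDN3 were not followed over the alternative settings. The list as a whole did not pass (camera adjusted p = 0.532; list score difference 0.07 ± 0.06).

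Among pattern recognition genes TLR4, the receptor for bacterial lipopolysaccharide, was raised (0.47 ± 0.15, SE) and PYCARD, the inflammasome adaptor, lowered (-0.54 ± 0.16) when adjusted over the list alone; the list did not pass (camera adjusted p = 0.183). Among serotonin and motility receptors the cannabinoid receptor gene CNR1 was raised over the list alone (0.47 ± 0.14, from 0.953 to 1.77 NPM; camera adjusted p = 0.282 for the list). Of heat shock genes HSPA1B (-0.42 ± 0.12) and HSPB1 (-0.62 ± 0.18) were lowered over the list alone (camera adjusted p = 0.653). MT-ND3 of the mitochondrial genome (-0.41 ± 0.13; camera adjusted p = 0.814 for the list) and the epithelial transcription factor gene CDX1 (-0.30 ± 0.09; camera adjusted p = 0.814 for the list) were lowered in the same way. Of adipocyte genes LPL was raised (0.34 ± 0.09) and CFD lowered (-0.46 ± 0.17), with a camera adjusted p of 0.945 for the list. These calls within lists were not adjusted over the 35 lists. In limma 27.2% of all tested genes had an unadjusted p below 0.05. The lists had 4 of 21 for pattern recognition, 3 of 17 for serotonin and motility receptors and 3 of 17 for heat shock. Mitochondrially encoded genes had 2 of 13, epithelium 8 of 33 and adipocytes 2 of 7.

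Muscle and nerve transcripts made up little of these libraries, which limits what lists of those cells can show. The smooth muscle contractile list took 0.441% of the library total in HV and 0.415% in PI-IBS, and the enteric neuron list 0.0151% and 0.0143%. With all 56 samples camera called no list of muscle, nerve or immune cell markers. Enteric glia came nearest, lower in 12 of 14 members with GFRA3 at -0.32 ± 0.11 (SE; camera adjusted p = 0.0511, and adjusted p = 0.979 with an estimated correlation), and camera called them lowered in 10 of 19 alternative settings. Smooth muscle ion channels were called raised within titles without TRNA (camera adjusted p = 0.0154, against 0.127 with all samples; adjusted p = 0.813 with an estimated correlation), and the smooth muscle contractile list lowered without PI-IBS replicate 27 (camera adjusted p = 0.0337, against 0.483; adjusted p = 0.995 with an estimated correlation). The smooth muscle contractile score differed by -0.07 ± 0.12, with a 95% interval from -0.31 to 0.16, and its lowest-p member MYL6 was at -0.33 ± 0.11. Camera's adjusted p was 0.740 for enteric neurons, 0.459 for interstitial cells of Cajal (the gut's pacemaker cells), 0.625 for macrophages, 0.949 for T and NK cells, 0.945 for mast cells, 0.328 for B and plasma cells and 0.364 for neutrophils and eosinophils. The summed share of the interstitial cell list was 0.0149% ± 0.00281 in HV and 0.0173% ± 0.00294 in PI-IBS (SD; permutation test, adjusted p = 0.0253); within the fewer titles without TRNA it was 0.0149% and 0.0175%, a difference as large that did not pass (adjusted p = 0.0590). Of its 7 tested members ELOVL6, a fatty acid elongase gene, had the largest difference in level, from 70.1 to 81.2 NPM (log2 difference 0.26 ± 0.13, not passing), beside KIT at 0.15 and ANO1 at 0.03, while the list score difference of 0.12 ± 0.05 had an adjusted p of 0.143. None of the 35 list scores passed after adjustment.

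**Figure D4:**
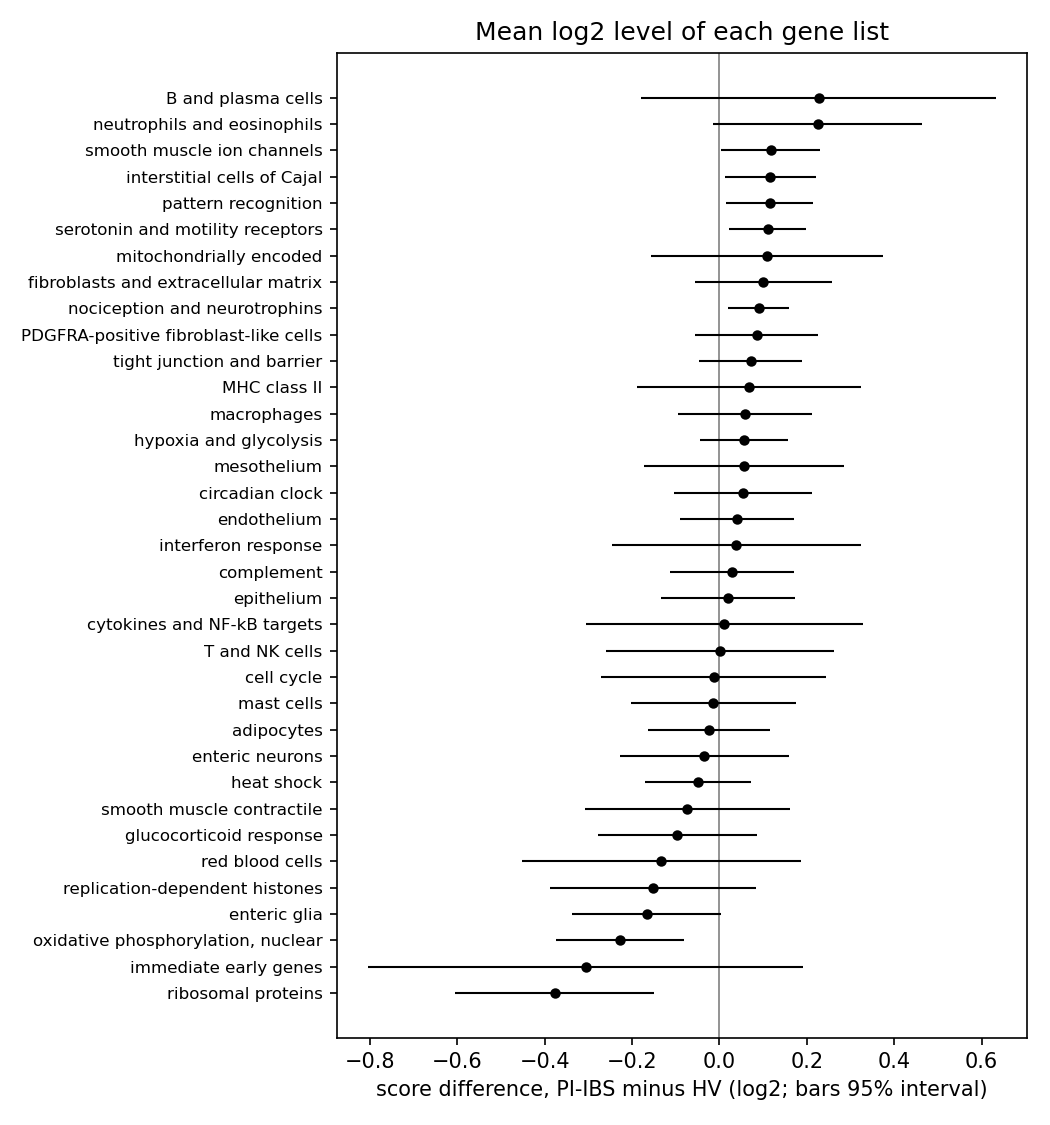
Difference of the mean log2 level of each of 35 gene lists, PI-IBS minus HV (x axis, log2 scale); points are differences and bars 95% intervals over samples, not adjusted for the 35 lists. Ribosomal proteins lie lowest at -0.38, and 0 lists passed the permutation test after adjustment.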

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

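The settings that took the number of genes listed at 0, the estimated reads or the first principal component as a covariate, and those without HV replicate 25 (the most genes at 0), PI-IBS replicate 27 (the highest smooth muscle share) or HV replicate 4 (the highest DUOX2 in HV), were chosen after seeing the data. The edgeR and DESeq2 tests planned for whole reads were not run, because whole reads could not be recovered. Of the alternative values of summary results, 170 kept their direction and side of the threshold or stayed at or close to their count. Another 45 counts moved, 13 values were weaker, 9 stronger and 0 reversed. A count close to the main one, such as 5 raised genes for 4, was taken as unmoved. Of single genes 581 kept their direction and side of the threshold, 30 were weaker, 50 stronger and 33 reversed. The 4 raised genes stayed with other pseudocounts, no filter, recomputed TMM factors and robust moderation, though C1orf220 was at 1.06 with a pseudocount of 0.1 and 0.25 with one of 5; at a floor of 5 NPM it was not tested and 3 stayed. The cause of the shifts was not tested, except where fewer samples or the construction shows it.

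The count of 4 raised and 0 lowered genes became 5 raised and 2 lowered with quantile normalization, 1102 and 1863 with sample weights, 408 and 796 with the smooth muscle and epithelium scores as covariates, and 2200 and 2510 with 2 principal components of the group-centred values, which by construction lower the residual spread and cannot remove a group shift. It became 226 and 454 without HV replicate 4, and 2 raised with sex-linked expression as covariates (2577 genes at an unadjusted p below 0.05), which left out GABRE and CCDC162P. It became 0 and 0 with the title form as covariate, in titles without TRNA (fewer samples), with genes at 0, with estimated reads or with the first principal component as covariate, without HV replicate 25 and with the Wilcoxon rank-sum test. At an unadjusted p below 0.05 the title-form covariate left 4518 genes, titles without TRNA 3861, the Wilcoxon test 4025, the fit without HV replicate 25 3580, estimated reads 1155, genes at 0 836 and the first component 693. With no effect 814 would be expected. The 1 candidate raised over the list alone became 3 with the 2 components, and 0 with the title form, in titles without TRNA, with sex-linked expression, genes at 0, estimated reads or the first component as covariate, without HV replicate 25, without PI-IBS replicate 27 and with the Wilcoxon test.

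For lists, 0 were lowered with an estimated correlation or with fry, where the medians stay -0.38 for ribosomal proteins, -0.27 for oxidative phosphorylation and -0.27 for immediate early genes. At the preset correlation camera called ribosomal proteins and oxidative phosphorylation lowered in 19 of 19 settings, also with genes at 0, estimated reads or the first component as covariate. Random splits of the samples gave a median of 10 called lists, so these calls carry little weight. The 0 raised lists became 3 with the title form and in titles without TRNA, 2 with estimated reads, and 1 with sex-linked expression, muscle and epithelium scores, genes at 0, the first component or without HV replicate 4; the 3 lowered became 5 with genes at 0, the first component or without PI-IBS replicate 27. Of lists not called with all samples, camera called enteric glia lowered in 10 of 19 settings, B and plasma cells raised in 4, smooth muscle ion channels raised in 3, endothelium and fibroblasts raised in 2 each, the smooth muscle contractile list lowered in 2, and neutrophils and eosinophils raised, interferon response raised and mitochondrially encoded genes lowered in 1 each; no list called in any of the 19 settings passed with an estimated correlation there (lowest adjusted p = 0.140). Immediate early genes no longer passed at a floor of 5 NPM (-0.30), with quantile normalization (-0.29), sample weights (-0.13), the 2 components (-0.27), without HV replicate 25 (-0.20) or without HV replicate 4 (-0.19). The 0 list scores past the threshold became 1 at a floor of 5 NPM (ribosomal proteins -0.38), 4 with the title form (-0.40, and oxidative phosphorylation -0.26), 6 with muscle and epithelium scores (-0.38 and -0.24), 6 with the 2 components (-0.38 and -0.23) and 4 without HV replicate 4 (-0.40 and -0.24). The muscle to epithelium relation was -0.14 in PI-IBS and no longer passed.

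Signs of candidates that never passed turned in some settings. TACR2 was at 0.020 with a pseudocount of 5, 0.044 with weights, 0.066 with the title form, 0.072 in titles without TRNA, 0.061 with muscle and epithelium scores, 0.020 with genes at 0, 0.0022 with reads and 0.011 with the first component. ANO1 was at -0.020 with weights, -0.031 with the title form, -0.015 without TRNA titles, -0.016 with sex-linked expression, -0.11 with genes at 0, -0.049 with reads, -0.099 with the first component and -0.018 without HV replicate 4. TPH1 was at -0.026 with weights, -0.00045 with the title form, -0.043 with sex-linked expression, -0.053 with genes at 0 and -0.18 with the first component. KIT was at -0.033 with genes at 0, -0.022 with reads and -0.17 with the first component, and MYH11 at -0.065 and -0.057 with genes at 0 and the first component and -0.020 without PI-IBS replicate 27. CXCL8 was at -0.055 with the title form, -0.16 without TRNA titles and -0.016 with the first component, IL1B at -0.18 and -0.011 in the latter 2 settings, and TNF at -0.0043 without TRNA titles.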

Other observations

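The tests of library complexity, of transcript length and GC content, of mucosal tissue and mislabelled libraries, and of the title form for DUOX2 were chosen after related results were seen, as were the genes named and the library left out in the next paragraph, and the bound past which an explanation counts as argued against was made stricter after the values were seen.

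Among genes at 5 NPM or more with an unadjusted p below 0.01, DUOX2, the epithelial enzyme that releases hydrogen peroxide at the gut surface, had the largest log2 difference, 1.58 ± 0.35 (SE, limma adjusted p = 0.0605, not passing). In 29 of 31 PI-IBS samples it lay above the HV median, although the HV mean of 25.9 ± 76.6 NPM (SD, n = 25) rests on HV replicate 4; without it the HV mean was 10.7 ± 8.36 (n = 24) against 39.8 ± 29.6 in PI-IBS (n = 31), and the log2 difference 1.795 ± 0.305 (limma adjusted p = 0.00346). That library was left out for its high DUOX2, which favours a difference. DUOXA2, the maturation factor of DUOX2, beside it on chromosome 15, was at 0.91 ± 0.29 (limma adjusted p = 0.0624; 26 of 31 above the HV median). CEACAM5, an epithelial adhesion gene, was at 0.49 ± 0.17, LAMA3, a basement membrane laminin, at 0.82 ± 0.27, and FER1L6 at 1.45 ± 0.42. The inflammation markers NOS2 and LCN2 were at -0.26 ± 0.27 and -0.08 ± 0.25, and without HV replicate 4 at -0.02 ± 0.17 and 0.07 ± 0.22. The raised side also held RN7SL1 (0.94 ± 0.23) and immunoglobulin segments such as IGHV3-15 (0.94 ± 0.26). The lower side was led by MIR7705 (-1.03 ± 0.32), MT-TT (-0.95 ± 0.24), MT-TD (-0.82 ± 0.18), TMSB4XP4 (-0.82 ± 0.26) and MT-TG (-0.80 ± 0.24). Picked from further along it were PYY, a gut hormone gene (-0.64 ± 0.23), ASCL2, a stem cell transcription factor gene (-0.66 ± 0.16), and RARRES2 (-0.73 ± 0.20). None of these passed the adjustment over all genes with all 56 samples.

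That DUOX2 is higher in PI-IBS is a hypothesis, found and tested on the same data. More epithelium in the PI-IBS samples is argued against, since with the epithelium score as a covariate the difference was 1.57 ± 0.37 (SE, n = 56). The DUOX2 difference was 1.293 ± 0.378 with the log2 number of genes at 0 as a covariate and 1.28 ± 0.37 with the log2 of the estimated reads (n = 55). Within titles without TRNA it was 1.528 ± 0.424 (n = 46). DUOX2 was picked for its large difference in these same samples, so what remains is likely overstated. With each of these settings limma called 0 genes. These values therefore cannot decide on library complexity, the number of reads or the title form as sources. The disease itself, transcript length and chance among 16274 genes stay open as untested. Over 16100 genes Spearman's rho between transcript length and log2 difference was 0.41.

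The lower ribosomal protein and oxidative phosphorylation transcripts may follow library complexity rather than disease. With the log2 number of genes at 0 as a covariate the ribosomal score difference shrank from -0.38 to -0.18 ± 0.091 (SE, n = 56) and the oxidative phosphorylation one from -0.23 to -0.10 ± 0.059, so that the 95% interval of each just takes in 0; the margin is thin, and because the number of genes at 0 itself differs between the groups, an effect of the disease on both stays open. With estimated reads as a covariate they were -0.23 ± 0.11 and -0.14 ± 0.074 (n = 55), too near the threshold for reads to be told apart from the groups, because depth differs between them. Transcript length and GC content stay open as sources. Length was that of each gene's longest annotated transcript, which need not be the one expressed, so matching on it cannot decide. Relative to 282 and 512 genes matched on that length, GC content and level, the differences stayed at -0.25 ± 0.083 and -0.14 ± 0.041. Those matched genes were themselves lower, by -0.13 ± 0.054 and -0.09 ± 0.036, and over 16100 genes Spearman's rho between transcript length and log2 difference was 0.41, across genes, which are not independent replicates.

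Muscle free of epithelium is argued against, because the epithelial share was above the smooth muscle share in 56 of 56 libraries. How much mucosal tissue each sample held, and how it came there, stays open. Of the epithelium list of 33 genes, 93.9% lay above the median tested gene in at least 90% of libraries. These transcripts had been seen to be abundant before that test was set, so it restates the pattern. A few mislabelled libraries are argued against, because the lowest ratio of epithelial to smooth muscle share over 56 libraries was 3.66. The labels name no dissection step, and no biological explanation was tested.

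Chance was checked with 100 splits of the samples into 31 and 25, the real one included. For the gene count 1 of 100 splits gave as many, the real one with 4 genes, and the highest other gave 2. That is the smallest share that 100 splits allow, in a fit and splits that do not take the title form into account. With the title form as a covariate, within titles without TRNA or without HV replicate 25 the count is 0. With each library left out in turn it ran from 0 to 1614. Chance is thus argued against only for the count of this 1 fit, and is not excluded. At an unadjusted p below 0.05 the real split gave 4421 genes, the highest other 3422 and the median other 570. For gene lists 100 of 100 splits gave at least the real 3, with 22 lists in the highest other and a median of 10, so chance cannot be excluded and the samples carry a structure that moves many lists together. For candidates over the list alone 8 of 100 splits gave at least 1, with 3 in the highest other, so chance cannot be excluded. With sample weights 4 of 49 random splits called at least 1 gene and the highest called 1826, against 2965 in the real split. With 2 group-centred principal components as covariates, 24 of 49 random splits called at least 1 gene and the highest called 3757, against 4710 in the real split.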
